A study of Macaca fascicularis with 6 samples.

How the data were processed

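The libraries came from corneal epithelial cells of wild-type cynomolgus monkeys, with 2 samples uninjured and 2 each at days 1 and 3 after corneal injury. Per the labels' protocols, cells were passed through a strainer and captured on the 10x Genomics Chromium controller, full-length cDNA was made, and libraries were built and sequenced with HIT-scISOseq. The labels name Cell Ranger and a NextSeq kit without a version or a role, so whether the gene tables come from short or long reads is not known; the aligner, the genome build, the annotation and the barcode filters are not given in the sources used here.

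For each sample the authors deposited a table of gene by cell barcode and a table of isoform by cell barcode, both of them whole-number count values. The files hold each value as an unnormalised count, and whether reads of 1 molecule were collapsed is not stated. Gene tables gave symbols or Ensembl identifiers and held no coordinates; a pairing of symbols with RefSeq records matched 0 of the Ensembl identifiers, so gene positions are not given. The total count per sample ranged from 3733442 to 4928103 in the gene tables and from 2218650 to 3197566 in the isoform tables. The 6 isoform tables used 2 naming systems with 0 identifiers in common: PB numbers in the uninjured samples and day 1 replicate 1, and Ensembl or numbered transcripts in day 1 replicate 2 and the day 3 samples. Isoform classes are those in the names: FSM matches a known transcript in full, ISM in part, NIC joins known splice sites in another combination and NNC uses at least 1 unknown splice site. In the Ensembl tables some barcodes were absent from the sample's gene table; only barcodes of the gene table were used, and all barcodes were an alternative.

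All 7895 deposited barcodes were used. Scrublet as run in scanpy 1.11.5 called 64 barcodes (0.811%) as doublets, and 68 barcodes had under 500 counts; these were left out only as alternatives. Counts were summed over the barcodes of a sample, since cells are not replicates. Sums of the 6 samples were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and the quasi-likelihood F test, with group as the only term and the Benjamini-Hochberg threshold at 0.05. The TMM factors were 1.19 and 1.19 in uninjured samples, 0.922 and 0.966 at day 1, and 0.888 and 0.891 at day 3; the biological coefficient of variation was 0.0651. Summed replicates differed beyond counting error, with a chi-square per degree of freedom of 1.95 between the uninjured samples, 4.79 at day 1 and 2.13 at day 3. The labels name no sequencing batch, and whether replicates were different animals is not stated.

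The 31 gene lists were written before the data were examined. They cover corneal differentiation, basal and limbal progenitors, stress keratins and alarmins, migration and matrix, EGF, TGF-beta, Notch, Wnt, immediate early genes, inflammation, interferon response, DNA replication, mitosis, p53 targets, glycolysis, oxidative phosphorylation, ribosomal proteins, heat shock, endoplasmic reticulum stress, NRF2 targets, desmosomes and tight junctions, cornified envelope, actin, splicing regulators, mitochondrially encoded transcripts, and markers of keratocytes, immune cells, melanocytes, conjunctival and goblet cells, vascular cells and red blood cells. The 29 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A member counts as risen or fallen when it passed edgeR's adjusted threshold over all genes. Counts with DESeq2 or totals alone are printed where one moved by over 1.5 times and at least 3 genes, or where the direction of the balance or of the median differed. Some lists share members.

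The rule for named genes, set before the data were examined, took up to 4 members of each list with the largest absolute log2 change among those past the threshold. It added the 5 genes with the highest and the 5 with the lowest change with an average log2 CPM of at least 5, separated replicates and a symbol, and 8 isoform genes per comparison. The text leaves out some of these, among them genes whose call was lost or whose fold moved strongly in an alternative. The 10 genes named for the classes were those with the highest or lowest change in that class; genes that lead the clusters being compared (among them VIM, COL17A1, PCK1, CYP26A1 and LY6D) were left out.

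For classes, counts per cell were log-normalised, centred and scaled within each sample, and clustered with Leiden (leidenalg 0.10.2) at resolution 0.5 on 2000 variable genes, 30 principal components and 15 neighbours. Clusters were named by marker lists, and the planned basal-like and differentiated-like classes were tested, since each sample held at least 50 of their cells; the conjunctival-like class was tested too, but added after seeing the data. Clusters stayed largely separate by group. Cluster 10 had the limbal marker CXCL14 and no basal marker among its leading genes. Clusters 4 and 11 were not named. Cluster 4, with 360 and 307 of the day 1 cells, had KRT14 and S100A2 among its leading genes, both on the basal and the limbal marker lists. Its cells are missing from the class tested as basal-like. Shares of classes were compared with an exact two-sided permutation test.

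Isoform usage was planned over all 6 samples. Because the names do not match, it was tested with diffSpliceDGE within each naming set, on isoforms with at least 10 counts in at least 2 samples, with the Simes method per gene; day 3 against uninjured was not tested. Isoforms per gene were counted with at least 2 counts, after thinning to 1 total, in genes with at least 100 thinned counts.

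Other settings planned beforehand were RLE scaling, DESeq2 1.42.0, no low-count filter, thinning to the smallest total, the barcode filters, only the 2 groups compared, the replicate number as a block, leaving out each sample, other clustering settings, another prior count, other isoform filters and a gene-level F test. A test against a 2-fold change (glmTreat), scaling to totals alone and all barcodes of the isoform tables were added after seeing the data. The test was tried on simulated data for the day 1 comparison, with 11845 genes run. Of these, 49 were made 1.5-fold higher, 46 1.5-fold lower, 50 2-fold higher and 49 4-fold higher, and the rest were unchanged. The test recovered 49.0% of the changes 1.5-fold higher and 34.8% of those 1.5-fold lower. It recovered 72% of the 2-fold and 98.0% of the 4-fold changes, and 10 of 134 calls were false. A shift of 20 points in isoform share was recovered in 32.3% of genes in the PB set and 80.1% in the Ensembl set. Figures were drawn with matplotlib 3.10.9; Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest.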

Results

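Epithelial cells were taken from the corneas of cynomolgus monkeys (Macaca fascicularis) that were uninjured (day 0), or at day 1 or day 3 after corneal injury, with 2 samples in each group. Single cells were captured as droplets on the 10x Genomics platform, and full-length cDNA was sequenced with HIT-scISOseq, a long-read method that reads whole transcripts and so separates the isoforms of a gene. The labels also name a NextSeq kit, so whether the gene counts come from short or long reads is not known. The tables held 7895 cell barcodes and 14623 genes, of which 12465 carried a gene symbol and 2158 only an Ensembl identifier. The uninjured samples held 1565 and 1417 barcodes with 4231412 and 4807975 counts, the day 1 samples 1482 and 1267 barcodes with 4928103 and 3733442 counts, and the day 3 samples 1096 and 1068 barcodes with 4894181 and 4584176 counts. Median counts per barcode were 2462 and 3023 in uninjured samples, 3258 and 2931 at day 1, and 4447 and 4145 at day 3. Mitochondrially encoded transcripts took 9.12% and 9.32% of counts in uninjured samples, 7.23% and 7.28% at day 1, and 4.52% and 4.39% at day 3. Across genes, log2 levels of the 2 samples of a group correlated with r = 0.988 when uninjured, 0.987 at day 1 and 0.989 at day 3. Genes are not independent replicates.

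Counts were summed per sample, and 12294 genes were tested with edgeR. Levels are counts scaled to library size by TMM (CPM), given as mean ± SD over the 2 samples of a group. A fold against a group with 0 counts is given as at least the fold against 3 counts over that group, and a group with 1 to 3 counts is given as a ratio with its exact counting interval. Intervals and floors cover counting error only. P-values measure only the spread between these samples, which may be technical, since the labels do not say whether the samples of a group came from different animals. All changes are relative to TMM scaling, under which the median log2 change over all genes was -0.06 at day 1 and -0.03 at day 3 against uninjured, and 0.02 at day 3 against day 1; with scaling to totals alone it was -0.40, -0.46 and -0.05, and in no list and comparison did more members rise or fewer fall. The gene lists were fixed before the data were examined, and a count adjusted over the list alone is printed where it differs from the count over all genes tested. For every gene named in the comparisons of all cells, both samples of one group lay above both samples of the other.

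The first comparison, day 1 against uninjured, asked which genes had changed 1 day after the injury. Lists of stress keratins and alarmins, inflammatory genes, migration and matrix genes and NRF2 targets were higher, while those of immediate early and cell cycle genes were lower. With an estimated correlation 0 of 29 lists passed (lowest adjusted p = 0.186). S100A9, a subunit of the antimicrobial protein calprotectin, reached 4375 ± 604 (SD, n = 2) against 109 ± 18.6 CPM (40.1-fold higher, adjusted p = 2.26e-10). HMOX1, the heme-degrading enzyme heme oxygenase 1, reached 476 ± 28.4 against 6.68 ± 0.425 CPM (70.9-fold higher, adjusted p = 2.87e-11). GPHA2, a marker of limbal stem cells, fell to 1.91 ± 0.831 against 205 ± 14.7 CPM (109.5-fold lower, adjusted p = 5.53e-10). KRT15, a keratin of limbal and basal cells, fell to 296 ± 18.5 against 3394 ± 202 CPM (11.5-fold lower, adjusted p = 2.26e-10). TXNIP, an inhibitor of thioredoxin that is induced by glucose, fell to 17.1 ± 0.186 against 656 ± 55.7 CPM (38.3-fold lower). PCK1, an enzyme of gluconeogenesis, fell to 4.76 ± 1.12 against 272 ± 34.2 CPM (58.0-fold lower).

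Among epithelial gene groups, the stress keratins and alarmins stood highest. Of 8 such genes, 7 rose, 1 fell and 0 did not pass, median log2 change 4.46 (camera adjusted p = 7.62e-04, adjusted p = 0.186 with an estimated correlation). PI3, the elastase inhibitor elafin, rose to 652 ± 176 (SD, n = 2) against 7.15 ± 2.22 CPM (89.9-fold higher). S100A8, the partner of S100A9, rose to 1755 ± 517 against 36.0 ± 5.03 CPM (48.5-fold higher). Among the 19 basal and limbal progenitor genes, 4 rose and 11 fell (4 and 12 adjusted over the list alone), 4 not passing, median log2 change -0.80 (camera adjusted p = 0.0684). This list passed without uninjured replicate 2 (adjusted p = 0.0365). S100A2, a calcium-binding protein of basal cells, rose to 2180.3 ± 567 against 135 ± 22.8 CPM (16.1-fold higher). In the corneal differentiation list (18 genes), 7 rose, 2 fell and 9 did not pass, median log2 change 0.00 and mean 0.38 (camera direction up, camera adjusted p = 0.302), while with DESeq2 7 rose, 2 fell and the median was 0.01 and with scaling to totals alone 5 rose, 9 fell and the median was -0.34. ALDH1A3, which makes retinoic acid, rose to 347 ± 2.56 against 24.7 ± 5.58 CPM (14-fold higher), and the differentiation keratin KRT24 rose to 2877 ± 30.6 against 1032 ± 162 CPM (2.79-fold higher). PAX6, the transcription factor that specifies the eye, was 2.17-fold lower at 267 ± 2.31 against 579 ± 23.0 CPM. The cornified envelope and superficial cell list held 13 genes, of which 9 rose, 2 fell and 2 did not pass, median log2 change 0.75 (camera adjusted p = 0.0684). It passed without uninjured replicate 2 (adjusted p = 0.0322), day 1 replicate 1 (0.0411) or day 1 replicate 2 (0.0444), and with no low-count filter (0.0460). For desmosomes and tight junctions, of 19 genes 14 rose, 1 fell and 4 did not pass, median log2 change 0.71 (camera adjusted p = 7.62e-04, adjusted p = 0.186 with an estimated correlation), while with scaling to totals alone 13 rose, 5 fell and the median was 0.38. DSG3, a desmosomal cadherin, rose to 769 ± 1.95 against 210.1 ± 2.63 CPM and the tight junction protein CLDN7 to 1064 ± 54.1 against 301 ± 11 CPM.

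The inflammatory list and the migration and matrix list were higher at day 1. Of 24 inflammatory cytokine and NF-kB genes, 21 rose, 0 fell and 3 did not pass, median log2 change 2.00 (camera adjusted p = 1.02e-07, adjusted p = 0.186 with an estimated correlation). IL1A, the alarmin interleukin-1 alpha, rose to 24.0 ± 5.28 (SD, n = 2) against 0 CPM (at least 84.6-fold higher). CSF3, the granulocyte growth factor G-CSF, rose to 17.8 ± 5.97 against 0 CPM (at least 65.7-fold higher). Of 28 migration and matrix remodelling genes, 23 rose, 1 fell and 4 did not pass, median log2 change 1.72 (camera adjusted p = 4.01e-08, adjusted p = 0.186 with an estimated correlation). The stromelysin MMP3 was at 15.9 ± 0.544 against 0 CPM (at least 57.3-fold higher), the gelatinase MMP9 at 4.95 ± 1.11 against 0 CPM (at least 18.1-fold higher) and the fibronectin receptor subunit ITGA5 at 5.55 ± 1.18 against 0 CPM (at least 20.3-fold higher). Of 19 actin cytoskeleton genes, 14 rose, 5 fell and 0 did not pass, median log2 change 1.23 (camera adjusted p = 0.00798, adjusted p = 0.186 with an estimated correlation). The membrane-actin linker MSN (moesin) was 5.71-fold higher at 73.8 ± 13.4 against 13 ± 0.357 CPM, whereas the tropomyosin TPM1 was 5.20-fold lower at 24.6 ± 0.869 against 128 ± 3.99 CPM. Among 26 interferon response genes, 12 rose, 5 fell and 9 did not pass, median log2 change 0.80 (camera adjusted p = 0.150), while with DESeq2 12 rose and 2 fell and with scaling to totals alone 12 rose, 10 fell and the median was 0.46 and the median was 0.35 with members at 0 counts set to their bound. IFI27 rose to 603 ± 164 against 124 ± 27.1 CPM and the antiviral GTPase MX2 to 5.61 ± 0.480 against 0 CPM (at least 20.3-fold higher). Among 11 EGF family genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone), 2 not passing, median log2 change 0.96 (camera adjusted p = 0.0789). It passed without uninjured replicate 2 (adjusted p = 0.0457). HBEGF, a ligand of the EGF receptor, rose to 409 ± 34.5 against 82.2 ± 4.64 CPM (4.97-fold higher), whereas EGF itself fell to 1.74 ± 0.283 against 13.6 ± 1.02 CPM (7.79-fold lower).

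Stress lists differed in direction at day 1. Of 15 NRF2 targets of the oxidative stress response, 11 rose, 1 fell and 3 did not pass, median log2 change 0.53 (camera adjusted p = 0.00147, adjusted p = 0.186 with an estimated correlation), while with scaling to totals alone 7 rose, 2 fell and the median was 0.19. Besides HMOX1, TXNRD1, which reduces thioredoxin, rose to 205 ± 7.70 (SD, n = 2) against 27.5 ± 1.40 CPM (7.45-fold higher) and the glutathione peroxidase GPX2 to 304 ± 66.8 against 29.4 ± 2.90 CPM. Among 16 endoplasmic reticulum stress genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), 3 not passing, median log2 change 0.49 (camera adjusted p = 0.00147, adjusted p = 0.186 with an estimated correlation), while with scaling to totals alone 7 rose, 2 fell and the median was 0.15. The stress transcription factor ATF4 rose to 624 ± 7.05 against 217 ± 10.5 CPM (2.88-fold higher) and the chaperone HSPA5 (BiP) to 771 ± 7.62 against 333 ± 2.35 CPM (2.32-fold higher). In the heat shock list of 10 genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone), 3 not passing, median log2 change 0.33 (camera adjusted p = 0.0789), while with scaling to totals alone 4 rose, 2 fell and the median was -0.01. HSPH1, a large chaperone, was 2.22-fold higher at 105 ± 4.86 against 47.5 ± 6.31 CPM. Of 18 p53 targets, 10 rose, 3 fell and 5 did not pass, median log2 change 0.63 (camera adjusted p = 0.0164, adjusted p = 0.213 with an estimated correlation). SFN, the cell cycle inhibitor 14-3-3 sigma, rose to 9137 ± 484 against 1399.9 ± 81.3 CPM (6.53-fold higher) and the stress cytokine GDF15 to 11.1 ± 0.0567 against 0 CPM (at least 39.7-fold higher). Among 21 immediate early genes, 2 rose, 15 fell and 4 did not pass, median log2 change -0.77 (camera adjusted p = 0.00246, adjusted p = 0.186 with an estimated correlation). FOS was 3.18-fold lower at 1339.7 ± 64.1 against 4266 ± 55.3 CPM and NR4A1 was 4.80-fold lower at 203 ± 5.30 against 975 ± 17.4 CPM, while FOSL1, a FOS-related factor, rose to 177 ± 6.26 against 28.4 ± 0.431 CPM.

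Cell cycle lists were lower at day 1, and lists of metabolism and gene expression were higher or did not pass. Of 24 DNA replication genes, 1 rose, 10 fell and 13 did not pass, median log2 change -0.50 (camera adjusted p = 0.0246, adjusted p = 0.186 with an estimated correlation), while with DESeq2 1 rose and 6 fell. The call ended without uninjured replicate 1 (adjusted p = 0.0811). MCM3, a subunit of the replicative helicase, had 0 (SD, n = 2) against 4.07 ± 0.407 CPM (at least 11.1-fold lower). Of 26 mitosis genes, 2 rose, 14 fell and 10 did not pass, median log2 change -1.88 (camera adjusted p = 0.0164, adjusted p = 0.588 with an estimated correlation), while the median was -1.66 with members at 0 counts set to their bound. This call ended without uninjured replicate 2 (adjusted p = 0.0965). The spindle checkpoint kinase BUB1 had 0 against 2.30 ± 0.441 CPM (at least 6.30-fold lower). Of 13 glycolysis genes, 10 rose, 1 fell and 2 did not pass, median log2 change 0.69 (camera adjusted p = 0.00379, adjusted p = 0.186 with an estimated correlation). The lactate transporter SLC16A3 rose to 87.9 ± 9.91 against 17.6 ± 0.734 CPM and hexokinase 2 (HK2) to 142 ± 6.71 against 50.4 ± 1.44 CPM. Among 19 nuclear genes of oxidative phosphorylation, 11 rose, 2 fell and 6 did not pass, median log2 change 0.37 (camera adjusted p = 0.114), while with DESeq2 4 rose and 0 fell and with scaling to totals alone 3 rose, 5 fell and the median was 0.03. It passed without day 1 replicate 2 (adjusted p = 0.00488). Of 29 ribosomal protein genes, 21 rose, 0 fell and 8 did not pass, median log2 change 0.38 (camera adjusted p = 0.00232, adjusted p = 0.579 with an estimated correlation), while with scaling to totals alone 3 rose, 2 fell and the median was 0.04. Of 28 splicing regulators, 18 rose, 3 fell and 7 did not pass, median log2 change 0.32 (camera adjusted p = 0.00689, adjusted p = 0.186 with an estimated correlation), while with scaling to totals alone 7 rose, 8 fell and the median was -0.01. PTBP1, a repressor of exon inclusion, was 1.99-fold higher.

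Signalling lists of TGF-beta, Notch and Wnt did not pass at day 1. Of 16 TGF-beta genes, 6 rose, 7 fell and 3 did not pass, median log2 change -0.11 (camera adjusted p = 0.509), while with scaling to totals alone 2 rose, 9 fell and the median was -0.45. The receptor TGFBR2 rose to 43.4 ± 0.598 (SD, n = 2) against 15.9 ± 0.840 CPM and ID2, an inhibitor of differentiation, fell to 36.2 ± 4.90 against 145 ± 7.88 CPM. Of 13 Notch genes, 4 rose, 8 fell and 1 did not pass, median log2 change -0.87 (camera adjusted p = 0.221). The ligand DLL1 rose to 29.7 ± 1.17 against 4.38 ± 0.280 CPM and the target HEY1 had 0 against 3.51 ± 0.459 CPM (at least 9.58-fold lower). Of 14 Wnt genes, 3 rose, 8 fell and 3 did not pass, median log2 change -0.66 (camera adjusted p = 0.0777). The ligand WNT10A fell to 2.24 ± 0.363 against 20.3 ± 2.04 CPM (9.04-fold lower). Of 13 mitochondrially encoded transcripts, 3 rose, 0 fell and 10 did not pass, median log2 change 0.11 (camera adjusted p = 0.285), while with scaling to totals alone 1 rose, 8 fell and the median was -0.23. Markers of other cell types of the ocular surface were measured beside these groups. Of 8 conjunctival and goblet cell markers, 7 rose, 1 fell and 0 did not pass, median log2 change 2.14 (camera adjusted p = 0.00689, adjusted p = 0.333 with an estimated correlation). The membrane mucin MUC1 rose to 105 ± 6.11 against 8.28 ± 0.120 CPM (12.6-fold higher) and KRT7, a keratin of conjunctival cells, to 54.1 ± 1.14 against 5.74 ± 0.513 CPM (9.34-fold higher). Of 7 keratocyte and fibroblast markers, 2 rose, 3 fell and 2 did not pass, median log2 change -1.20 (camera adjusted p = 0.450), while with DESeq2 2 rose and 2 fell and the median was -1.16 with members at 0 counts set to their bound. The matrix proteoglycan DCN fell to 194 ± 11.1 against 478 ± 86.8 CPM. Of 6 immune cell markers, 3 rose, 1 fell and 2 did not pass, median log2 change 0.56 (camera adjusted p = 0.210). The lysosomal protein CD68 rose to 36.0 ± 4.09 against 4.71 ± 0.741 CPM. Of 6 melanocyte markers, 0 rose, 2 fell and 4 did not pass, median log2 change -0.21 (camera adjusted p = 0.294). The receptor KIT fell to 8.77 ± 0.553 against 59.1 ± 8.39 CPM. Of the vascular list 4 genes were tested, 1 of which rose and 1 fell, and 0 of 6 red blood cell transcripts had a count.

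In total 7646 of 12294 genes passed at day 1, 3751 of them higher and 3895 lower, and 15 of 29 gene lists passed, 12 higher and 3 lower. DESeq2 called 4623 genes (55.1% higher), a test against a 2-fold change 2001, and scaling to totals alone 8190, of which 29.1% rather than 49.1% were higher.

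**Figure D1:**
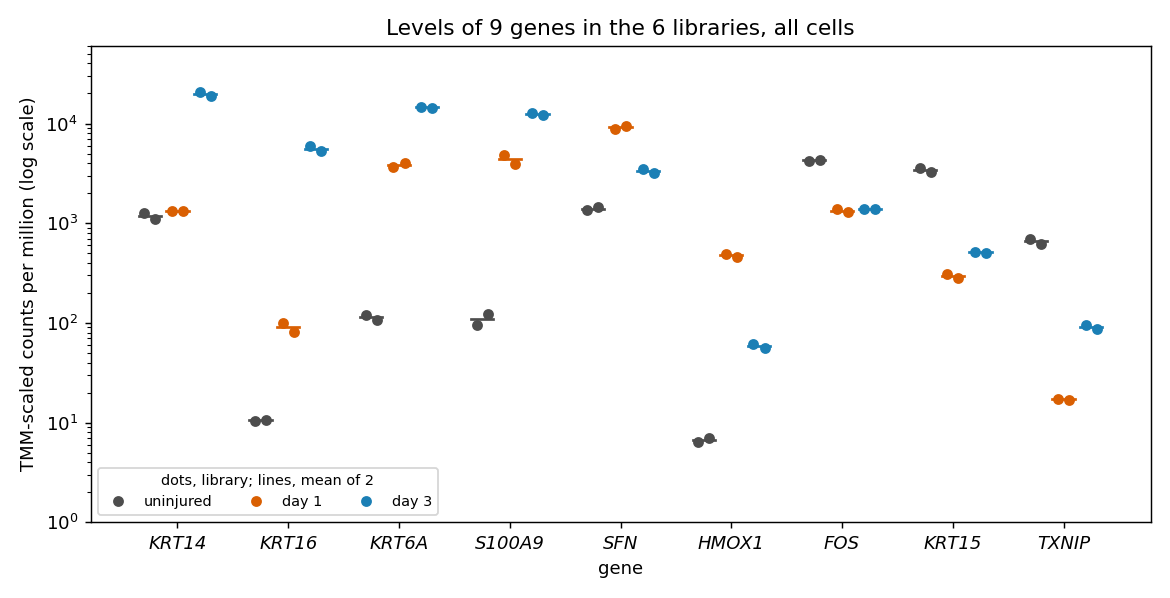
Levels of 9 genes in TMM-scaled CPM on a log10 axis, in uninjured samples and at days 1 and 3 after injury. Each dot is 1 sample and each short line marks the mean of 1 group (n = 2 samples). The KRT14 means lie at 1193, 1325 and 19852 CPM.

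The second comparison, day 3 against uninjured, asked which genes differed from the uninjured epithelium 3 days after the injury. Lists of stress keratins and alarmins, matrix, actin, interferon response, cornified envelope and cell cycle genes were higher, and those of mitochondrially encoded transcripts and immediate early genes lower. With an estimated correlation 0 of 29 lists passed (lowest adjusted p = 0.116). KRT14, a keratin of basal cells, reached 19852 ± 1172 (SD, n = 2) against 1193 ± 119 CPM (16.6-fold higher, adjusted p = 1.12e-10), KRT16, a keratin of wounded epithelium, 5604 ± 475 against 10.5 ± 0.197 CPM (532-fold higher, adjusted p = 5.32e-12) and KRT6A, its partner, 14521 ± 372 against 113 ± 8.28 CPM (128-fold higher, adjusted p = 5.32e-12). FN1, the matrix protein fibronectin, reached 512 ± 56.7 against 0.199 ± 0.282 CPM (2760.2-fold higher, exact counting interval 764 to 22799.5), and its fitted log2 change of 11.23 was 14.16 without uninjured replicate 1 and 10.23 without uninjured replicate 2. CYP26A1, which degrades retinoic acid, fell to 13.1 ± 2.27 against 489 ± 40.0 CPM (37.0-fold lower).

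Of 5 epithelial lists, 3 passed at day 3, all of them higher. Of 8 stress keratins and alarmins, 8 rose, 0 fell and 0 did not pass, median log2 change 6.10 (camera adjusted p = 2.50e-07, adjusted p = 0.239 with an estimated correlation). S100A8 stood at 4481 ± 286 (SD, n = 2) against 36.0 ± 5.03 CPM (124-fold higher) and S100A9 at 12498 ± 427 against 109 ± 18.6 CPM (114-fold higher). Of 13 cornified envelope and superficial cell genes, 13 rose, 0 fell and 0 did not pass, median log2 change 2.64 (camera adjusted p = 5.38e-05, adjusted p = 0.252 with an estimated correlation). CRCT1, a gene of the cornified cell layers, was at 15.4 ± 5.56 against 0 CPM (at least 54.9-fold higher), and SPINK5, an inhibitor of the proteases that shed skin, at 1115 ± 87.5 against 8.12 ± 5.29 CPM (134-fold higher). Without uninjured replicate 2 the log2 change of SPINK5 was 7.98 rather than 7.06. Among 19 basal and limbal progenitor genes, 8 rose and 7 fell (9 and 8 adjusted over the list alone), 4 not passing, median log2 change 0.15 and mean -0.56 (camera direction up, camera adjusted p = 0.881), while with scaling to totals alone 5 rose, 10 fell and the median was -0.27. GPHA2 had 0 against 205 ± 14.7 CPM (at least 576-fold lower) and S100A2 stood at 2450.2 ± 331 against 135 ± 22.8 CPM (18.1-fold higher). Among 18 corneal differentiation genes, 6 rose, 9 fell and 3 did not pass, median log2 change -0.16 and mean 0.11 (camera direction down, camera adjusted p = 0.455). ALDH1A3 rose to 407 ± 0.889 against 24.7 ± 5.58 CPM, while the water and glycerol channel AQP3 fell to 495 ± 18.5 against 1370.3 ± 19.8 CPM (2.77-fold lower). Of 19 desmosome and tight junction genes, 12 rose, 3 fell and 4 did not pass, median log2 change 0.31 (camera adjusted p = 0.0125, adjusted p = 0.252 with an estimated correlation), while with scaling to totals alone 6 rose, 6 fell and the median was -0.11.

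Lists of matrix, actin and immune response genes were higher at day 3. Of 28 migration and matrix remodelling genes, 27 rose, 1 fell and 0 did not pass, median log2 change 1.98 (camera adjusted p = 1.00e-10, adjusted p = 0.116 with an estimated correlation). TNC, the matrix protein tenascin-C, was at 29.1 ± 0.116 (SD, n = 2) against 0 CPM (at least 104-fold higher) and MMP9 at 22.7 ± 1.18 against 0 CPM (at least 81.3-fold higher). Of 19 actin cytoskeleton genes, 18 rose, 0 fell and 1 did not pass, median log2 change 1.39 (camera adjusted p = 5.82e-09, adjusted p = 0.116 with an estimated correlation). TAGLN, an actin-binding protein of contractile cells, rose to 148 ± 0.513 against 2.99 ± 0.281 CPM (49.2-fold higher, adjusted p = 6.60e-10) and TMSB10, which binds actin monomers, to 5099 ± 403 against 578 ± 11.8 CPM (8.82-fold higher). Of 24 inflammatory genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone), 3 not passing, median log2 change 1.44 (camera adjusted p = 7.04e-05, adjusted p = 0.239 with an estimated correlation). IL1A stood at 9.29 ± 1.42 against 0 CPM (at least 33.2-fold higher) and CCL2, a chemokine for monocytes, at 5.74 ± 1.93 against 0 CPM (at least 20.4-fold higher). Of 26 interferon response genes, 20 rose and 2 fell (21 and 3 adjusted over the list alone), 4 not passing, median log2 change 1.53 (camera adjusted p = 7.99e-06, adjusted p = 0.252 with an estimated correlation). OAS2, a sensor of double-stranded RNA, was at 20.5 ± 2.62 against 0 CPM (at least 73.7-fold higher) and MX2 at 9.54 ± 3.78 against 0 CPM (at least 34.5-fold higher). Stromal and conjunctival markers moved beside these groups. Of 7 keratocyte and fibroblast markers, 5 rose, 1 fell and 1 did not pass, median log2 change 3.46 (camera adjusted p = 0.0464, adjusted p = 0.252 with an estimated correlation). The call ended without day 3 replicate 1 (adjusted p = 0.0596) and with a prior count of 0.5 (0.0598). The proteoglycan LUM was at 29.5 ± 0.300 against 0 CPM (at least 106-fold higher) and COL1A2, a chain of type I collagen, at 17.4 ± 1.11 against 0 CPM (at least 62.2-fold higher). Of 8 conjunctival and goblet cell markers, 8 rose, 0 fell and 0 did not pass, median log2 change 3.10 (camera adjusted p = 2.82e-04, adjusted p = 0.252 with an estimated correlation). KRT7 rose to 408 ± 14.1 against 5.74 ± 0.513 CPM (70.5-fold higher) and MUC1 to 157 ± 9.15 against 8.28 ± 0.120 CPM.

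The DNA replication and mitosis lists were higher at day 3 than in uninjured samples. Of 24 DNA replication genes, 12 rose, 3 fell and 9 did not pass, median log2 change 0.66 (camera adjusted p = 0.0185, adjusted p = 0.252 with an estimated correlation), while with DESeq2 6 rose and 1 fell and with scaling to totals alone 11 rose, 6 fell and the median was 0.24. TYMS, which makes thymidylate, rose to 90.8 ± 3.53 (SD, n = 2) against 10.3 ± 1.27 CPM (8.78-fold higher, adjusted p = 1.70e-08) and RRM2, a subunit of ribonucleotide reductase, to 28.9 ± 5.31 against 3.18 ± 0.298 CPM (9.03-fold higher). Of 26 mitosis genes, 17 rose, 1 fell and 8 did not pass, median log2 change 1.16 (camera adjusted p = 0.00257, adjusted p = 0.574 with an estimated correlation), while with DESeq2 7 rose and 1 fell. The mitotic cyclin CCNB1 rose to 22.5 ± 4.19 against 4.24 ± 0.917 CPM (5.23-fold higher) and CKS2, a binding partner of cyclin-dependent kinases, to 193 ± 4.88 against 53.9 ± 8.62 CPM (3.57-fold higher). Of 18 p53 targets, 11 rose and 4 fell (12 and 4 adjusted over the list alone), 3 not passing, median log2 change 0.57 (camera adjusted p = 0.0185, adjusted p = 0.252 with an estimated correlation). SFN was 2.40-fold higher at 3356 ± 231 against 1399.9 ± 81.3 CPM. Of 21 immediate early genes, 5 rose, 15 fell and 1 did not pass, median log2 change -0.80 (camera adjusted p = 0.0125, adjusted p = 0.252 with an estimated correlation). FOS was 3.07-fold lower at 1389.9 ± 16.5 against 4266 ± 55.3 CPM, while CCN1 and CCN2, secreted targets of the YAP pathway, stood 4.40-fold higher and 7.81-fold higher. Of 11 EGF family genes, 5 rose, 4 fell and 2 did not pass, median log2 change 0.08 (camera adjusted p = 0.695), while with scaling to totals alone 4 rose, 6 fell and the median was -0.35. EGF had 0 against 13.6 ± 1.02 CPM (at least 38.1-fold lower).

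At day 3 the list of nuclear genes of mitochondrial respiration was higher and that of mitochondrially encoded transcripts lower. Of 29 ribosomal protein genes, 29 rose, 0 fell and 0 did not pass, median log2 change 0.83 (camera adjusted p = 6.56e-08, adjusted p = 0.338 with an estimated correlation). RPLP0 rose to 5195 ± 101 (SD, n = 2) against 2145 ± 24.4 CPM (2.42-fold higher). Of 19 nuclear genes of oxidative phosphorylation, 16 rose, 0 fell and 3 did not pass, median log2 change 0.81 (camera adjusted p = 4.56e-04, adjusted p = 0.353 with an estimated correlation), while with scaling to totals alone 11 rose, 3 fell and the median was 0.38. NDUFB2, a complex I subunit, rose to 375 ± 43.2 against 153 ± 9.60 CPM. Of 13 mitochondrially encoded transcripts, 0 rose and 10 fell (0 and 11 adjusted over the list alone), 3 not passing, median log2 change -0.56 (camera adjusted p = 0.00138, adjusted p = 0.272 with an estimated correlation). MT-ATP6, an ATP synthase subunit, fell to 5719 ± 281 against 9849 ± 265 CPM (1.72-fold lower). Of 13 glycolysis genes, 9 rose, 2 fell and 2 did not pass, median log2 change 0.42 (camera adjusted p = 0.0125, adjusted p = 0.252 with an estimated correlation), while with scaling to totals alone 6 rose, 4 fell and the median was 0.00. Of 10 heat shock genes, 7 rose, 0 fell and 3 did not pass, median log2 change 0.62 (camera adjusted p = 0.00364, adjusted p = 0.252 with an estimated correlation), while with scaling to totals alone 5 rose, 3 fell and the median was 0.20. Of 16 endoplasmic reticulum stress genes, 8 rose, 3 fell and 5 did not pass, median log2 change 0.28 (camera adjusted p = 0.161), while with scaling to totals alone 4 rose, 7 fell and the median was -0.14. Of 15 NRF2 targets, 10 rose, 3 fell and 2 did not pass, median log2 change 0.56 (camera adjusted p = 0.0733), while with scaling to totals alone 3 rose, 5 fell and the median was 0.13. HMOX1 stood at 58.6 ± 4.45 against 6.68 ± 0.425 CPM (8.72-fold higher). Of 28 splicing regulators, 6 rose, 11 fell and 11 did not pass, median log2 change -0.16 (camera adjusted p = 0.199), while with DESeq2 0 rose and 6 fell and with scaling to totals alone 0 rose, 23 fell and the median was -0.58. SRSF7, a serine/arginine-rich splicing factor, fell to 180.3 ± 7.44 against 380.1 ± 0.993 CPM (2.11-fold lower).

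Other lists did not pass at day 3. Of 16 TGF-beta genes, 6 rose, 8 fell and 2 did not pass, median log2 change -0.19 and mean 0.31 (camera direction down, camera adjusted p = 0.604). The ligand TGFB1 rose to 64.7 ± 2.53 (SD, n = 2) against 21.1 ± 0.254 CPM, TGFB2 fell to 11.9 ± 0.145 against 62.0 ± 5.30 CPM, and the inhibitor SMAD7 rose to 73.2 ± 4.26 against 26.1 ± 0.573 CPM. Of 13 Notch genes, 3 rose, 6 fell and 4 did not pass, median log2 change -0.32 and mean 0.24 (camera direction down, camera adjusted p = 0.471), while with DESeq2 2 rose and 3 fell. The receptor NOTCH2 fell to 36.6 ± 2.30 against 83.8 ± 11.7 CPM. Of 14 Wnt genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone), 4 not passing, median log2 change -0.76 (camera adjusted p = 0.161). SFRP1, a secreted Wnt antagonist, rose to 53.6 ± 4.68 against 2.07 ± 0.457 CPM (25.9-fold higher). Of 6 immune cell markers, 2 rose, 2 fell and 2 did not pass, median log2 change -0.04 and mean -0.06 (camera direction up, camera adjusted p = 0.776), while with DESeq2 2 rose and 1 fell and with scaling to totals alone 1 rose, 2 fell and the median was -0.47. Of 6 melanocyte markers, 0 rose, 3 fell and 3 did not pass, median log2 change -0.19 (camera adjusted p = 0.421). KIT fell to 16.6 ± 2.96 against 59.1 ± 8.39 CPM. In the vascular list 2 of 4 tested genes rose and 1 fell. PCK1 had 0 against 272 ± 34.2 CPM (at least 768-fold lower) and PENK, the precursor of enkephalin peptides, 0 against 85.7 ± 10.9 CPM (at least 239-fold lower).

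In total 6792 of 12294 genes passed at day 3 against uninjured, 3545 higher and 3247 lower, and 18 of 29 lists passed, 16 higher and 2 lower. DESeq2 called 3590 genes (64.1% higher against 52.2%), a test against a 2-fold change 1433, and scaling to totals alone 8182, of which 24.2% were higher.

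**Figure D2:**
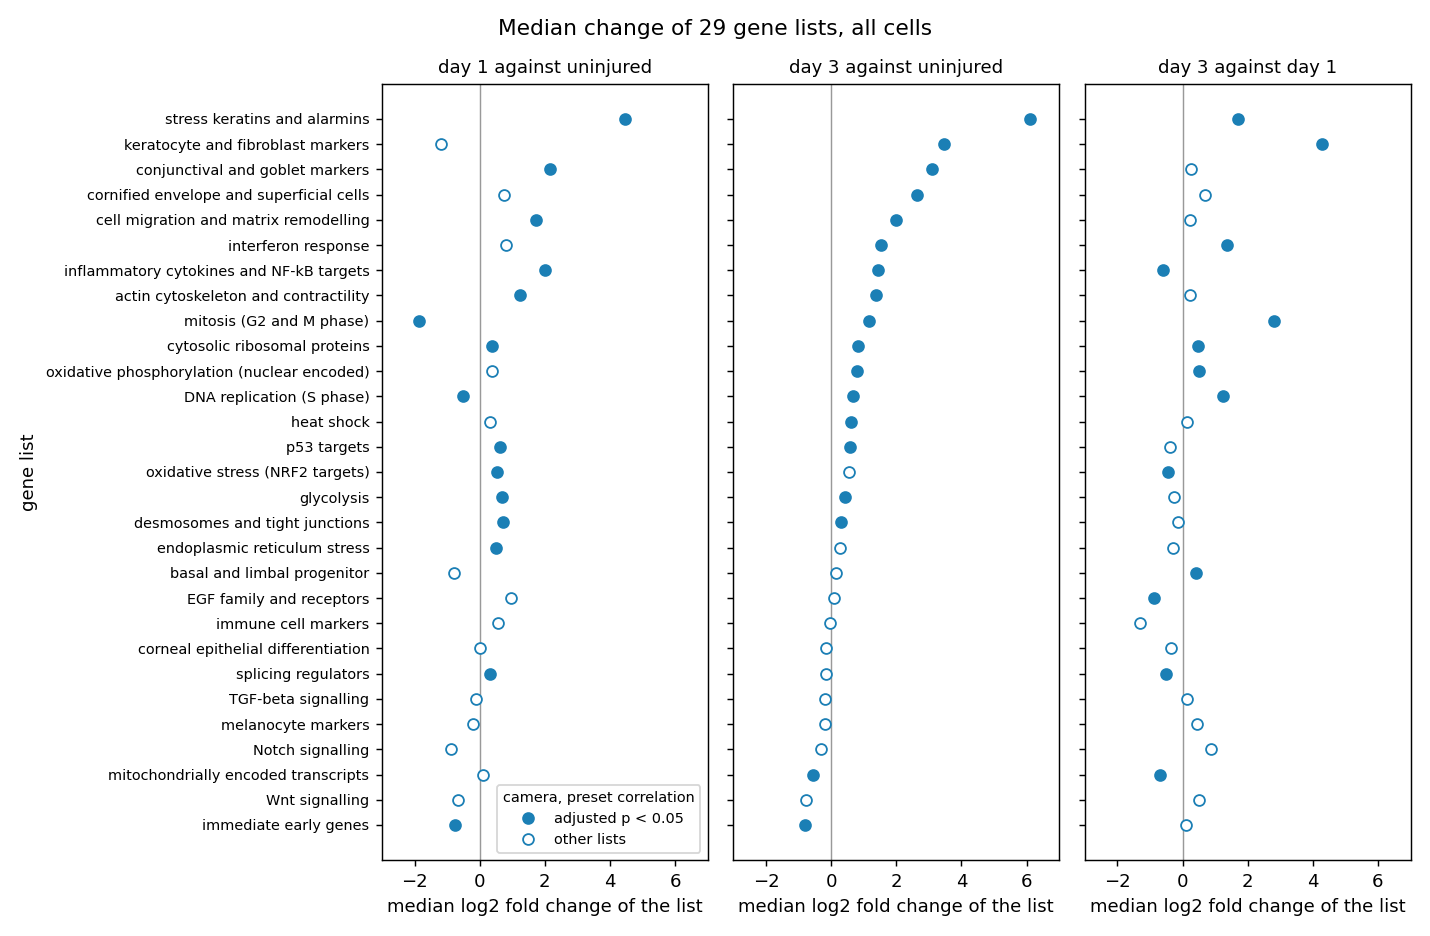
Median log2 fold change of the tested members of 29 gene lists in the 3 comparisons, with TMM scaling. Each dot is 1 list, filled where the camera adjusted p was under 0.05; with scaling to totals alone the median of all genes lay at -0.40, -0.46 and -0.05, and the median of some lists near 0 changed sign.

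The third comparison, day 3 against day 1, asked which genes changed between the samples taken at these times. Lists of cell cycle, interferon response and ribosomal genes were higher at day 3, while those of NRF2 targets, EGF family genes, splicing regulators and mitochondrially encoded transcripts were lower. With an estimated correlation 0 of 29 lists passed (lowest adjusted p = 0.341). KRT14 was 15-fold higher at 19852 ± 1172 (SD, n = 2) against 1325 ± 5.73 CPM (adjusted p = 2.88e-10), KRT16 61.9-fold higher at 5604 ± 475 against 90.2 ± 13.3 CPM (adjusted p = 1.50e-10) and SPINK5 at least 3021-fold higher at 1115 ± 87.5 against 0 CPM (adjusted p = 4.57e-09). HMOX1 fell to 58.6 ± 4.45 against 476 ± 28.4 CPM (8.13-fold lower, adjusted p = 7.78e-10), and CSF3 had 0 against 17.8 ± 5.97 CPM (at least 51.4-fold lower). TNNT3, a troponin best known from fast skeletal muscle, fell to 21.5 ± 2.47 against 470.0 ± 0.0148 CPM (21.8-fold lower).

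The cell cycle lists were higher at day 3. Of 26 mitosis genes, 24 rose, 1 fell and 1 did not pass, median log2 change 2.81 (camera adjusted p = 6.78e-05, adjusted p = 0.520 with an estimated correlation). The kinase AURKB was at 6.23 ± 2.63 (SD, n = 2) against 0 CPM (at least 16.8-fold higher) and BUB1 at 5.04 ± 2.24 against 0 CPM (at least 13.5-fold higher). Of 24 DNA replication genes, 19 rose, 1 fell and 4 did not pass, median log2 change 1.25 (camera adjusted p = 4.96e-04, adjusted p = 0.341 with an estimated correlation), while with DESeq2 12 rose and 1 fell. MCM3 was at 11.4 ± 0.507 against 0 CPM (at least 30.9-fold higher). Of 18 p53 targets, 4 rose and 10 fell (5 and 10 adjusted over the list alone), 4 not passing, median log2 change -0.38 (camera adjusted p = 0.261), while with DESeq2 4 rose and 6 fell. SFN fell to 3356 ± 231 against 9137 ± 484 CPM (2.72-fold lower). Of 21 immediate early genes, 9 rose and 7 fell (10 and 7 adjusted over the list alone), 5 not passing, median log2 change 0.09 (camera adjusted p = 0.643), while with scaling to totals alone 9 rose, 9 fell and the median was 0.01. CCN2 was 8.48-fold higher and CCN1 5.61-fold higher, and FOSL1 was 3.74-fold lower. Of 11 EGF family genes, 2 rose, 9 fell and 0 did not pass, median log2 change -0.89 (camera adjusted p = 0.0150, adjusted p = 0.341 with an estimated correlation). HBEGF fell to 130.1 ± 7.83 against 409 ± 34.5 CPM (3.14-fold lower).

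Of 8 stress keratins and alarmins, 6 rose, 2 fell and 0 did not pass, median log2 change 1.72 (camera adjusted p = 0.0212, adjusted p = 0.356 with an estimated correlation). KRT17, another keratin of wounded epithelium, was 5.96-fold higher at 1413 ± 61.0 (SD, n = 2) against 237 ± 8.92 CPM and KRT6A was 3.77-fold higher. Of 19 basal and limbal progenitor genes, 11 rose, 4 fell and 4 did not pass, median log2 change 0.41 (camera adjusted p = 0.0411, adjusted p = 0.510 with an estimated correlation). This call ended without day 1 replicate 1 (adjusted p = 0.0605), day 1 replicate 2 (0.10), day 3 replicate 1 (0.0564) or day 3 replicate 2 (0.0819). POSTN, the matrix protein periostin, rose to 20.1 ± 0.724 against 2.24 ± 0.363 CPM. Of 18 corneal differentiation genes, 4 rose and 11 fell (5 and 11 adjusted over the list alone), 3 not passing, median log2 change -0.37 (camera adjusted p = 0.0779). AQP3 fell to 495 ± 18.5 against 1289 ± 4.11 CPM. Of 13 cornified envelope genes, 8 rose, 1 fell and 4 did not pass, median log2 change 0.68 (camera adjusted p = 0.0663). It passed without day 1 replicate 1 (adjusted p = 0.0302). KRT78, a keratin of superficial cells, rose to 179 ± 13.7 against 4.32 ± 1.74 CPM (42.7-fold higher). Of 19 desmosome and tight junction genes, 6 rose, 9 fell and 4 did not pass, median log2 change -0.15 (camera adjusted p = 0.342). CLDN7 was 3.33-fold lower, and occludin (OCLN) was 3.19-fold lower. Of 28 migration and matrix genes, 13 rose, 13 fell and 2 did not pass, median log2 change 0.23 (camera adjusted p = 0.860), while with DESeq2 12 rose and 10 fell and with scaling to totals alone 12 rose, 13 fell and the median was 0.15. The collagenase MMP13 was at 19.5 ± 3.22 against 0 CPM (at least 52.8-fold higher) and VIM, the intermediate filament vimentin, at 626 ± 34.9 against 20.5 ± 8.71 CPM (31.3-fold higher). Of 19 actin genes, 9 rose, 5 fell and 5 did not pass, median log2 change 0.24 (camera adjusted p = 0.0851). TPM1 rose to 491 ± 0.658 against 24.6 ± 0.869 CPM (adjusted p = 1.50e-10) and CALD1, which regulates actomyosin, to 214 ± 3.95 against 26.5 ± 2.48 CPM (8.02-fold higher). Beside these, of 7 keratocyte and fibroblast markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone), 2 not passing, median log2 change 4.29 (camera adjusted p = 0.00370, adjusted p = 0.341 with an estimated correlation), while the median was 4.12 with members at 0 counts set to their bound. COL1A1 was 57.1-fold higher at 50.5 ± 9.35 against 0.857 ± 0.0347 CPM. Of 8 conjunctival and goblet cell markers, 4 rose, 3 fell and 1 did not pass, median log2 change 0.27 (camera adjusted p = 0.332). KRT7 rose to 408 ± 14.1 against 54.1 ± 1.14 CPM.

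Immune and stress lists parted between the days. Of 26 interferon response genes, 19 rose, 3 fell and 4 did not pass, median log2 change 1.37 (camera adjusted p = 7.76e-04, adjusted p = 0.356 with an estimated correlation). OAS3 rose to 13.3 ± 0.754 (SD, n = 2) against 2.10 ± 0.167 CPM (6.30-fold higher). Of 24 inflammatory genes, 4 rose, 15 fell and 5 did not pass, median log2 change -0.60 (camera adjusted p = 0.0411, adjusted p = 0.356 with an estimated correlation), while with DESeq2 3 rose and 9 fell. This call ended without day 1 replicate 1 (adjusted p = 0.0605) or day 3 replicate 1 (0.0974). BIRC3, an inhibitor of apoptosis, fell to 18.4 ± 2.38 against 59.9 ± 3.49 CPM. Of 15 NRF2 targets, 1 rose, 11 fell and 3 did not pass, median log2 change -0.44 (camera adjusted p = 0.0171, adjusted p = 0.341 with an estimated correlation), while with DESeq2 1 rose and 7 fell. TXNRD1 fell to 41.1 ± 0.817 against 205 ± 7.70 CPM (4.98-fold lower). Of 16 endoplasmic reticulum stress genes, 3 rose and 8 fell (3 and 9 adjusted over the list alone), 5 not passing, median log2 change -0.29 (camera adjusted p = 0.113). ATF4 fell to 232 ± 7.50 against 624 ± 7.05 CPM. Of 10 heat shock genes, 5 rose, 1 fell and 4 did not pass, median log2 change 0.15 (camera adjusted p = 0.348), while with scaling to totals alone 5 rose, 4 fell and the median was 0.07. The small chaperone HSPB1 rose to 3034 ± 51.7 against 1511 ± 77.5 CPM. Of 6 immune cell markers, 0 rose, 3 fell and 3 did not pass, median log2 change -1.31 (camera adjusted p = 0.245). CD74, the invariant chain of MHC class II, fell to 6.56 ± 1.47 against 43.7 ± 15.5 CPM and CD68 to 11.3 ± 0.675 against 36.0 ± 4.09 CPM. Of 6 melanocyte markers, 2 rose, 1 fell and 3 did not pass, median log2 change 0.43 and mean -0.70 (camera direction up, camera adjusted p = 0.443). In the vascular list 2 of 4 tested genes rose and 1 fell, and with scaling to totals alone 1 rose and 1 fell.

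Of 29 ribosomal protein genes, 22 rose, 0 fell and 7 did not pass, median log2 change 0.48 (camera adjusted p = 4.96e-04, adjusted p = 0.602 with an estimated correlation). Of 19 nuclear genes of oxidative phosphorylation, 13 rose and 2 fell (14 and 2 adjusted over the list alone), 4 not passing, median log2 change 0.49 (camera adjusted p = 0.0411, adjusted p = 0.602 with an estimated correlation). The call ended without uninjured replicate 1 (adjusted p = 0.0617), uninjured replicate 2 (0.0611), day 1 replicate 2 (0.10), day 3 replicate 1 (0.0513) or day 3 replicate 2 (0.0931). Of 13 mitochondrially encoded transcripts, 0 rose, 11 fell and 2 did not pass, median log2 change -0.70 (camera adjusted p = 4.96e-04, adjusted p = 0.356 with an estimated correlation). MT-ND6 fell to 98.0 ± 5.36 (SD, n = 2) against 274 ± 44.1 CPM. Of 28 splicing regulators, 1 rose and 19 fell (1 and 20 adjusted over the list alone), 8 not passing, median log2 change -0.52 (camera adjusted p = 4.96e-04, adjusted p = 0.341 with an estimated correlation). SRSF7 fell to 180.3 ± 7.44 against 511 ± 17.2 CPM (2.83-fold lower) and HNRNPH1 to 189 ± 15.4 against 392 ± 8.74 CPM (2.08-fold lower). Of 13 glycolysis genes, 5 rose, 4 fell and 4 did not pass, median log2 change -0.27 and mean 0.01 (camera direction down, camera adjusted p = 0.860), while with DESeq2 4 rose and 4 fell and with scaling to totals alone 4 rose, 6 fell and the median was -0.36. Of 16 TGF-beta genes, 7 rose, 5 fell and 4 did not pass, median log2 change 0.13 (camera adjusted p = 0.711). SMAD7 rose to 73.2 ± 4.26 against 10.0 ± 0.755 CPM and SMAD3, a mediator of the pathway, fell to 29.1 ± 1.90 against 91.9 ± 5.59 CPM. Of 13 Notch genes, 7 rose, 3 fell and 3 did not pass, median log2 change 0.88 (camera adjusted p = 0.225). LFNG, which modifies Notch receptors, rose to 10.3 ± 1.73 against 1.08 ± 0.346 CPM and DLL1 fell to 5.12 ± 0.395 against 29.7 ± 1.17 CPM. Of 14 Wnt genes, 8 rose, 2 fell and 4 did not pass, median log2 change 0.49 (camera adjusted p = 0.108), while with DESeq2 5 rose and 2 fell. SFRP1 rose to 53.6 ± 4.68 against 8.71 ± 0.151 CPM.

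In total 7294 of 12294 genes passed at day 3 against day 1, 3750 higher and 3544 lower, and 13 of 29 lists passed, 8 higher and 5 lower. DESeq2 called 4317 genes and a test against a 2-fold change 1588, of which 63.2% rather than 51.4% were higher, and scaling to totals alone 7309, of which 46.0% were higher.

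Cells were grouped into classes by clustering and named by marker genes. Each class holds mostly a different cluster in each group, so its values compare different sets of cells and do not separate a change within a class from a change in its cells. The first set holds mostly clusters 9, 10 and 8 in uninjured, day 1 and day 3 samples, which are compared by number: CXCL14, a limbal marker, was among the leading genes of clusters 8 and 10, COL17A1, a basal marker, among those of cluster 8 only, and cluster 9 had no marker there. Cluster 4, which held 360 and 307 day 1 cells and had KRT14 and S100A2 among its leading genes, was not part of this set. Cells of this set numbered 219 and 178 in uninjured samples, 192 and 166 at day 1, and 258 and 253 at day 3. In them HMOX1 rose at day 1 to 961 ± 17.2 (SD, n = 2) against 4.92 ± 0.305 CPM (188-fold higher) and KRT27, a keratin of the hair follicle sheath, to 207 ± 13.5 against 3.28 ± 0.203 CPM (59.9-fold higher), while TXNIP fell to 5.87 ± 0.897 against 439 ± 96.5 CPM (73.6-fold lower). CYP24A1, which degrades active vitamin D, had 0 against 48.6 ± 13.2 CPM (at least 16.8-fold lower). At day 3 against uninjured, FN1 had 326 ± 15.4 against 0 CPM (at least 134-fold higher) and the laminin chain LAMB4 fell to 13.4 ± 0.343 against 255 ± 35.5 CPM (18.7-fold lower). Against day 1, APOE, a lipid carrier, CCDC80, a matrix protein, and SEMA3C, a guidance molecule, which had 0 counts at day 1, stood at 190.2 ± 1.62, 134 ± 21.6 and 83.3 ± 1.67 CPM. HBEGF fell to 33.8 ± 6.74 against 490.4 ± 80.7 CPM (14.5-fold lower) and HMOX1 to 73.7 ± 3.99 against 961 ± 17.2 CPM (13-fold lower). Of 7617 genes tested, 2346 passed at day 1 (1188 higher), 2708 at day 3 (1497 higher) and 2933 between the days (1557 higher). DESeq2 called 714 (69.5% rather than 50.6% higher), 1001 (67.2% rather than 55.3%) and 1061, a test against a 2-fold change 358, 562 and 533, and with scaling to totals alone 34.7% of the calls at day 3 and 38.8% of those between the days (53.1% with TMM) were higher.

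Differentiated corneal epithelial-like cells (mostly clusters 2, 0 and 6) numbered 463 and 436 in uninjured samples, 613 and 530 at day 1, and 285 and 277 at day 3. At day 1 CCL20, a chemokine for dendritic and T cells, had 147 ± 40.6 (SD, n = 2) against 0 CPM (at least 215-fold higher), and CYP26B1, which degrades retinoic acid, 481 ± 30.0 against 7.39 ± 1.02 CPM (63.9-fold higher), while KRT15 fell to 8.38 ± 3.37 against 595 ± 92.0 CPM (68.8-fold lower) and KRT19 to 22.7 ± 5.87 against 527 ± 33.3 CPM (22.8-fold lower). At day 3 against uninjured, KRT14 stood at 22057 ± 382 against 46.4 ± 20.7 CPM (466-fold higher, adjusted p = 4.35e-18). KRT16 stood at 10469 ± 669 against 1.11 ± 0.844 CPM and its fitted log2 change was 13.05, or 14.11 without uninjured replicate 2. Against day 1, KRT16 was 501-fold higher, KRT14 131-fold higher and IFI6, an interferon-induced protein, 32.9-fold higher at 701 ± 107 against 21.0 ± 3.45 CPM. CCL20 fell to 3.40 ± 1.38 against 147 ± 40.6 CPM (43.3-fold lower) and KRT23 to 7.54 ± 0.751 against 300.5 ± 28.7 CPM (39.3-fold lower). Of 9969 genes tested, 5487 passed at day 1 (2727 higher), 4312 at day 3 (2286 higher) and 4987 between the days (2556 higher). DESeq2 called 2413 (62.7% rather than 49.7% higher), 1990 (67.1% rather than 53%) and 2404, and a test against a 2-fold change 1157, 899 and 962 (61.6% rather than 51.3% higher between the days); with scaling to totals alone 30.1%, 21.6% and 40.8% of calls were higher.

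Shares are read for the cycling-like class alone, though genes that lead its cluster, as of the others, changed between the groups. Cycling-like cells made up 1.20% ± 0.701 (SD, n = 2) of barcodes in uninjured samples, 0.580% ± 0.0388 at day 1 and 5.50% ± 0.427 at day 3. The exact two-sided permutation p was 0.333 for each pair of groups, the smallest that 2 samples against 2 allow, so this test cannot pass 0.05 here.

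Isoform usage, the share of a gene's counts that each isoform takes, could be compared only among samples whose isoform tables used the same naming. The 2 uninjured samples and day 1 replicate 1 used one set of isoform names, day 1 replicate 2 and the 2 day 3 samples used another, and 0 names were shared, so day 1 stands as a single sample on either side and day 3 was not compared with uninjured. Isoform tables held 2591000, 3102684 and 3197566 counts in the first set and 3008974, 2400594 and 2218650 in the other. In day 1 replicate 1 against uninjured, usage passed in 488 of 4103 genes (963 with a gene-level F test) and in 136 of 1086 with 50 or more counts. With 1 sample at day 1 and 1 residual degree of freedom in each set, the lone sample is assumed to vary like the pair it is compared with, so a change at day 1 is not told apart from a difference of that library. In APOBEC3A, a cytidine deaminase induced by interferon, the isoform PB.155.352, a full match to a known transcript, took 89.7% (95% Wilson interval 89.5 to 90.0) of counts at day 1 against 70.2% ± 2.17 (SD, n = 2) in uninjured samples (adjusted p = 9.75e-10). In EZR, the membrane-actin linker ezrin, PB.43337.2845, with at least 1 splice site outside the reference, took 2.61% (95% Wilson interval 2.21 to 3.08) against 11.4% ± 1.56 (adjusted p = 1.60e-06), and in the DNA topoisomerase TOP1, PB.2432.169, a partial match, took 1.67% (95% Wilson interval 1.16 to 2.40) against 13.5% ± 0.888 (adjusted p = 7.43e-06). In KRT12, a keratin of the corneal epithelium, PB.18846.2216 took 86.5% (95% Wilson interval 86.1 to 86.9) against 89.6% ± 0.101 (adjusted p = 5.51e-05), and in cytoplasmic actin ACTG1, PB.19305.109 took 95.7% (95% Wilson interval 95.4 to 95.9) against 88.6% ± 0.176 (adjusted p = 7.67e-05). In UBE2D3, a ubiquitin-conjugating enzyme, PB.47860.153 took 11.9% (95% Wilson interval 10.4 to 13.5) against 18.7% ± 0.199 (adjusted p = 7.67e-05), in ADIRF, PB.62303.625 took 18.8% (95% Wilson interval 18.2 to 19.3) against 15.5% ± 0.216 (adjusted p = 9.12e-05), and in CD55, an inhibitor of complement, PB.29803.92 took 13.9% (95% Wilson interval 12.4 to 15.6) against 3.63% ± 1.64 (adjusted p = 9.12e-05). These 3 isoforms join known splice sites in combinations outside the reference. The counts of isoforms that fully match a known transcript were 61.2%, 62.5% and 62.6% of the total in the first set.

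At day 3 against day 1 replicate 2, usage passed in 2 of 519 genes, 1 of which has no symbol. In all, 22 genes had an unadjusted gene p under 0.05, and a gene-level F test in place of the Simes method called 8 and all barcodes 5. In ADH1B, an alcohol dehydrogenase, ENSMFAT00000018864 took 2.86% (95% Wilson interval 2.33 to 3.50) of counts at day 1 and 9.94% ± 0.264 (SD, n = 2) at day 3 (adjusted p = 0.0200). In ERICH5 the named isoform took 30.6% (95% Wilson interval 28.1 to 33.2) at day 1 and 60.7% ± 1.36 at day 3, which did not pass (adjusted p = 0.0805), and in PPP1CC, a catalytic subunit of protein phosphatase 1, 17.2% (95% Wilson interval 13.9 to 21.0) and 36.8% ± 3.02, which did not pass either (adjusted p = 0.145). These shares rest on 1234 of 1267 barcodes of the gene table at day 1 and on 701 of 1096 and 679 of 1068 at day 3, the others being absent from the isoform tables. In this set 78.8% of counts at day 1, and 82.2% and 81.3% at day 3, were full matches. The mean number of isoforms per gene after thinning was 6.05 and 6.47 in uninjured samples and 6.98 in day 1 replicate 1 over 2309 genes. With 5 or more counts asked of an isoform, these were 5.97, 5.98 and 6.14. In the other set the mean was 1.17 in day 1 replicate 2 and in both day 3 samples over 1797 genes. No permutation test of 1 sample against 2 can pass 0.05.

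**Figure D3:**
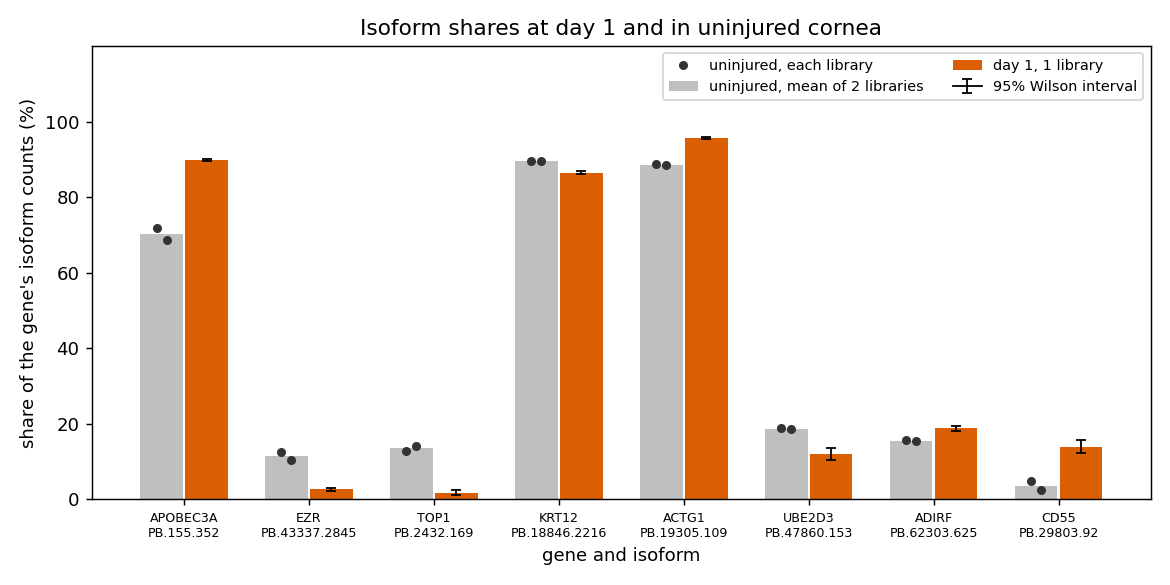
Share of the gene's isoform counts, in percent, taken by the named isoform of 8 genes in uninjured samples and at day 1, in the set of tables that share isoform names. Each dot is 1 uninjured sample and each grey bar their mean; the orange bar is the single day 1 sample with its 95% Wilson interval.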

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

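The tests of depth, of a single gene, TUBB4B, and of processing by sets of samples were chosen only after the results were seen, as were the counts of cells by cycling markers. The DNA replication list moved down at day 1 and up at day 3 against uninjured, and its median log2 change at day 3 against day 1 was 1.25. The mitosis list did the same with a median of 2.81. With an estimated correlation neither passed: at day 1, at day 3 and between the days the adjusted p = 0.186, 0.252 and 0.341 for DNA replication and 0.588, 0.574 and 0.520 for mitosis. At day 1 the lower call of the DNA replication list ended without uninjured replicate 1 (adjusted p = 0.0811) and that of the mitosis list without uninjured replicate 2 (adjusted p = 0.0965).

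The tables argue against a difference in counts per sample as the source of the rise in the mitosis list: day 1 replicate 1 held more counts than either day 3 sample, and without day 1 replicate 2 the list's median was still 2.59. The first count of cells went the other way: with every cell thinned to 1500 counts, cells with at least 3 counts of the mitosis list made up 15.4% and 18.8% of uninjured, 16.6% and 18.6% of day 1 and 11.4% and 13.3% of day 3 cells. TUBB4B, a tubulin that most clusters express, is a candidate explanation for this disagreement, since it took 58.2% and 50.2% of the list's counts in uninjured, 71.2% and 72.2% in day 1 and 32.5% and 29% in day 3 samples; without it day 3 stood at 7.35% and 8.77%, above 1.89% and 3.34% in uninjured and 1.30% and 1.55% in day 1 samples. Cells with at least 2 counts of the cycling markers were 3.70% and 4.09%, 0.996% and 1.65%, and 7.54% and 9.72%. The time after injury stays open as a biological explanation and was not tested apart from the samples.

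The change against uninjured differed between clusters 9, 10 and 8 and differentiated-like cells in 406 of 9980 genes at day 1. It was more positive in differentiated-like cells for 193 and less for 213. At day 3, 1004 differed (479 and 525). The interaction term had samples as blocks and 3 residual degrees of freedom. The counts are left unexplained.

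Isoform tables held counts in barcodes outside the sample's gene table, which no main comparison used: 3.73% of isoform counts in day 1 replicate 2, 9.77% in day 3 replicate 1 and 9.53% in day 3 replicate 2, against 0 in the samples whose isoforms carry PB numbers. These samples carry other isoform names, and a difference in processing that also reached the gene tables could appear as a change at day 3. Over the 6792 genes called at day 3 against uninjured, the slope of day 1 replicate 2 minus day 1 replicate 1 on the day 3 change was -0.0289. This argues against such a difference as the source of those calls as a whole. The slope cannot exclude it for single genes. The day 1 samples, split between the sets, had a chi-square per degree of freedom of 4.79. It was 1.95 and 2.13 for the uninjured and day 3 pairs, each within 1 set.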

How the results depend on the processing

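The test against a 2-fold change, scaling to totals alone and all barcodes of the isoform tables were chosen only after the results were seen; the other alternatives were planned. Counts of changed genes stayed within 1.5 times their value under RLE scaling, totals alone, no low-count filter, each left-out sample and a fit of only the 2 groups compared, and in all cells, where alone they were run, under thinning and the barcode and doublet filters. DESeq2 called fewer genes: 4623, 3590 and 4317 in all cells for day 1 against uninjured, day 3 against uninjured and day 3 against day 1, then 714, 1001 and 1061 in clusters 9, 10 and 8 and 2413, 1990 and 2404 in differentiated-like cells, and the cause was not tested. The test against a 2-fold change, which asks for more by construction, called 2001, 1433 and 1588, then 358, 562 and 533, then 1157, 899 and 962. Genes called in the same direction in every setting other than the 2-fold test numbered 4094 (53.5%), 2968 (43.7%) and 4018 (55.1%) in all cells, 683, 944 and 1027 in clusters 9, 10 and 8, and 2200, 1665 and 2220 in differentiated-like cells. Of the day 3 calls in all cells, 20 had the opposite direction with scaling to totals alone. Leaving out 1 sample at a time gave 6536 to 7740, 5531 to 7329 and 6178 to 7186 genes in all cells, 1614 to 2401, 2028 to 2938 and 2324 to 3060 in clusters 9, 10 and 8, and 4333 to 5495, 3189 to 4601 and 3828 to 4945 in differentiated-like cells, with the lone sample assumed to vary like the others.

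The count of gene lists fell to 0, 0 and 0 with an estimated correlation and was 26, 23 and 28 with fry, which does not compare a list with other genes; leaving out 1 sample gave 14 to 17, 17 to 18 and 10 to 12. Over single lists 853 values kept their side of the threshold, 63 no longer passed, 40 newly passed and 1 passed in the other direction, the EGF list at day 3 against uninjured, lower with a fry adjusted p of 0.00209; lists that turned without passing are among those that kept their side. Values of named genes kept their side 6521 times and lost the call 253 times; those of isoform genes 62 times, with 9 newly passing. Isoform usage passed in 136 of 1086 genes at day 1 against uninjured with 50 or more counts. A gene-level F test gave 963, and 8 at day 3 against day 1, where all barcodes gave 5. Why these gave more was not tested. The difference in isoforms per gene at day 1 against uninjured was 0.161 with 5 or more counts, and at day 1 against day 3 it was -0.00223 with 1 or more counts, in the other direction, and 0.00250 with 5 or more. Leaving out a sample and the replicate block left no residual degrees of freedom for isoforms, and day 3 against uninjured was not run.

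Shares of classes moved with the clustering and are not read as changes of cell types. Without centring within samples, the differences in points were -41.6, -41.6 and 0 for limbal-like cells, 9.60 (day 3 minus uninjured) and 10.1 (day 3 minus day 1) for clusters named basal-like, and 5.36 (day 3 minus day 1) for cycling-like cells. Differentiated-like cells then differed by 2.89 at day 3 minus uninjured, reversed from -4.21, and by -8.80 at day 3 minus day 1. Conjunctival-like cells differed by 5.95 at day 1 and 14.7 at day 3 minus uninjured, both reversed from -12.2 and -3.13. At resolution 1.0 limbal-like cells differed by -0.287 (day 3 minus day 1). Differentiated-like cells differed there by 10.5 (day 1 minus uninjured), 1.96 (day 3 minus uninjured, reversed) and -8.55 (day 3 minus day 1), and conjunctival-like cells by 4.67 and 2.16 at days 1 and 3 minus uninjured, both reversed, and by -2.50 at day 3 minus day 1, reversed from 9.09. Without doublets the limbal-like difference at day 3 minus day 1 was -0.477 against -0.473. The superficial-like class had no cells without centring, so it has no value there.

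With the replicate number as a block, 7302, 6421 and 6959 genes passed in all cells, 2162, 2553 and 2778 in clusters 9, 10 and 8 and 5371, 4220 and 4879 in differentiated-like cells, and 15, 18 and 13 lists. The block carries no pairing: over 4385 genes, differences between replicates correlated by 0.105, -0.0206 and -0.259 between pairs of groups.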

Other observations

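The tests of the cluster described here were chosen only after its values were seen. Conjunctival epithelial-like cells, a class for which no comparison was planned, also differed between groups. At day 1 IDO1, which degrades tryptophan, stood at 70.2 ± 21.2 CPM (SD, n = 2) against 0 in uninjured samples, DHRS9, a retinol dehydrogenase, at 345 ± 13.5 against 0.793 ± 0.284, and SERPINA3, an acute-phase protease inhibitor, at 175 ± 33.6 against 0.248 ± 0.351. At day 3 ARG1, which cleaves arginine, stood at 257 ± 42.6 CPM against 0 in uninjured samples, the matrix protein osteopontin (SPP1) at 132 ± 3.27 against 0, and GABRP, a GABA receptor subunit, at 121 ± 4.65 against 0. TNNT3 stood at 6.59 ± 0.413 CPM at day 3 and 1383 ± 50.1 at day 1. The class compares different clusters at each time, as for the other classes, and at clustering resolution 1.0 it held 207 and 215 rather than 487 and 464 uninjured cells, so that falls from uninjured levels are left out here.

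At day 3, 101 and 92 cells (9.22% and 8.61%) formed a cluster set apart by fibronectin, collagen and tenascin-C transcripts. Its counts held FN1 at 5014 and 4845 and COL1A1 at 674 and 589 CPM of its total. These genes define the cluster and are not a result in themselves. Its KRT14 level was 104% of that of other day 3 cells in the lower library. COL3A1 stood at 6.81 and 4.03 CPM and the keratocyte gene KERA at 0 in both. KRT14 was high across day 3 cells, so its level cannot exclude stromal keratocytes or fibroblasts. The tables argue against droplets that hold an epithelial and a stromal cell. The cluster's median counts per barcode were 0.607 times those of other day 3 cells in the higher library. Stromal cells and epithelial cells that express matrix genes both stay open as hypotheses. Free RNA in the droplets was not tested.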
